A study of Arabidopsis thaliana with 83 samples.

How the data were processed

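Transcript levels were measured on Affymetrix ATH1 arrays in whole seedlings of 7 natural accessions of Arabidopsis thaliana, Bay-0, Bl-1, Bur-0, C24, Col-0, Fei-0 and Sha. The labels name Bay-0 as the ecotype of its 12 arrays but also call them a recombinant inbred line, and they were taken here as Bay-0, so what is reported for Bay-0 rests on that reading. Per the labels, stratified seed (5 days in the cold) was grown for 7 days in shaken liquid culture at 22 °C in constant light, and a yellow filter stood in the light path for the last 24 h. Samples were labelled 0 h, 30 min, 1 h and 3 h, which gave 28 groups and 83 arrays, with 3 arrays per group and 2 for Fei-0 at 3 h. The serial numbers in the titles run through the accessions in turn, and through the times in turn within each accession. Neither accession nor time can therefore be told apart from any order or batch of processing. The auxin dose, a hybridisation date and mock-treated arrays at the later times are not given in the sources used here. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. For arrays no depth per sample applies, and the number of arrays limits the precision.

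The deposited table held signal intensity values, 1 per probe set and array, on a linear scale. The submitters' processing notes name MAS5 and GCOS, with versions not given in the sources used here. The trimmed mean signal, without the lowest and highest 2% of values, was 100 in every array, so the deposited values had been scaled to a common level. The deposited values covered 22810 probe sets, of which 64 Affymetrix controls were left out of the comparisons and used only for 3'/5' signal ratios. Of the other 22746, 13513 were listed with 1 gene, 503 with several and 8730 with none. Genes were named only from those with 1 gene, 13436 of them matched by gene identifier and 48 by locus tag, and no gene coordinates were used. Well-known auxin genes such as IAA5, IAA19 and SAUR15 had no listed probe set and carry no value here.

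Signals were taken as log2(signal + 16). The 30% of probe sets with the lowest mean, 6824, were left out, which left 15922, of which 8674 had 1 gene. Models were fitted in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with 1 mean per group, a shared spread over all 83 arrays and a trended prior, with 55 residual and 13.2 prior degrees of freedom. The contrasts were the response averaged over the 7 accessions at each time, the response of each accession against its own 0 h arrays (21 contrasts), the steps from 30 min to 1 h and from 1 h to 3 h, the difference in response between accessions (moderated F test at each time), and the level at 0 h (moderated F test). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold, or for the F tests a range over the accessions of at least 1 on the log2 scale. Values are log2 changes with the standard error (SE) of the model, or mean signals with the standard deviation (SD) between arrays. The SE and p of a mean response rest on the spread between arrays of a group, not on that between accessions. All p-values printed for genes are adjusted p from limma, two-sided.

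Gene lists used 1 probe set per gene, that with the highest mean. There were 28 lists fixed before the data were examined, as were the tests, thresholds, settings and the rule for named genes. A further 22 gene families, taken by symbol prefix, were added before any test was run but after the files were given. Lists with at least 3 measured genes (29 lists, 7 of the 28 fixed ones) were tested in limma with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, with adjustment over 87 tests. A gene is called measured here if a probe set listed with it alone passed the filter. Of the fixed lists, 11 had no member matched to a probe set with 1 gene. On hormones they were auxin response factors, auxin receptors, ethylene biosynthesis, brassinosteroid, gibberellin and cytokinin metabolism, and the jasmonate pathway. The others were core cell cycle, heat shock, flowering time, and seed storage. Probe sets with no listed gene may still measure members of these lists. A difference between accessions in the response of the Aux/IAA, GH3 and SAUR lists was tested with a one-sided permutation test of an F statistic on list scores, with 100000 permutations and adjustment over 9 tests.

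The rule for named genes took, among called probe sets with 1 gene, the 8 largest mean changes up and down at each time with the same sign in all 7 accessions. It also took up to 4 called members of each list, GH3.3, HAT2 and LBD29 in every accession, the 2 largest changes up and down per accession at 1 h, the 8 smallest p for a difference in response at each time, and the 5 largest steps each way. For levels at 0 h it took the 10 smallest p, the 10 largest ranges and up to 3 members per list. Genes outside the rule are named as list members or as chosen after their values were seen.

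The model was tested on simulated data with 15922 probe sets and 200 changed ones per comparison, at log2 sizes of 1.2, 1.5 and 2. For the mean response at 1 h it recovered 98.5%, 100% and 100%. For the response of Sha at 1 h it recovered 95.5%, 100% and 100%. For the difference in response at 1 h it recovered 98.5%, 98.5% and 100%, with 4 false calls. For levels at 0 h it recovered 100% at each size, with 1 false call, and for the step from 1 h to 3 h 100% at each size. Of 100 simulated lists of 20 genes shifted by 0.3, camera at 1 h detected 100%, and the list permutation test detected 96% of 200 simulated scores with 1 accession changed and 4% of 200 unchanged ones. The simulated genes were drawn independently and most real lists were shorter, so this does not show how camera performs on short or correlated lists.

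Alternatives changed the pseudocount to 1 or 64, the normalization to quantile normalization or median centring, the filter to none or the lowest 50%, added the replicate number as a block, fitted each accession separately, and left out each array, replicate number or accession in turn. The GAPDH 3'/5' ratio as a covariate, and some of the removals of an accession, were added after seeing the data. For the pooled comparisons 100 splits of the same arrays were counted, the real one included. Time labels were shuffled within accessions for the mean response and steps, and accession labels among the 0 h arrays for levels at 0 h. For the difference in response, residuals of a model of accession plus time were shuffled between arrays within each time. Figures were drawn with matplotlib 3.10.9 and tables joined with pandas 2.3.3 in Python 3.11.15.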

Results

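Whole seedlings of 7 Arabidopsis accessions were profiled on 83 arrays at 4 times labelled by the length of auxin treatment. Each of the 28 groups held 3 arrays, except Fei-0 at 3 h, which held 2. The median signal of an array lay between 38 and 43.2. Arrays of the same group correlated across probe sets at r = 0.964 to 0.991 (median 0.984), where probe sets are not independent replicates. Of the variance of the tested probe sets, 59.6% lay between accessions, time added 13.9%, accession by time added 11.4%, and 15% lay between replicates. The 3'/5' signal ratio of the GAPDH control, a sign of RNA quality, ran from 1.41 ± 0.07 in Sha at 3 h to 2.99 ± 1.23 in C24 at 1 h (SD, n = 3), and that of actin from 2.57 ± 0.46 in Bay-0 at 3 h to 105 ± 43.4 in Col-0 at 0 h (SD, n = 3). Group means of the actin ratio were 2.57 to 5.57 in Bay-0 and 62.9 to 105 in Col-0 over the times. Those of GAPDH overlapped, at 1.64 to 2.1 and 1.93 to 2.92. The actin ratio alone therefore does not show that RNA quality differed between these accessions.

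The series title names natural variation of the auxin response, and the response shared by the accessions was taken up before their differences. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, showed the largest mean rise among named genes, by 4.23 ± 0.05 on the log2 scale at 30 min, 5.34 ± 0.05 at 1 h and 5.20 ± 0.05 at 3 h (SE of the model, 83 arrays, without the spread between accessions). In limma the adjusted p was 1.09e-65, 1.48e-72 and 2.8e-71. LBD29, a transcription factor of lateral root initiation, rose by 3.1 ± 0.07, 3.6 ± 0.07 and 3.52 ± 0.07 at the same times. Its signals at 0 h, 4.12 to 14.1, lay under the pseudocount, so the size of its rise depended on that choice and was 5.11 at 1 h with 1 added and 2.22 with 64 added. HAT2, a class II HD-Zip factor, rose by 3.1 ± 0.05 at 30 min and by 1.36 ± 0.05 at 3 h. All 3 genes were higher in each of the 7 accessions at each time.

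In the mean over accessions 97 probe sets were higher and 19 lower at 30 min, 129 and 24 at 1 h, and 109 and 94 at 3 h. The share of calls that were higher was 83.6%, 84.3% and 53.7%. With no minimum fold, 3759, 4979 and 6973 probe sets passed the adjusted p. Of the called probe sets, 113 of 116, 153 of 153 and 190 of 203 had the same sign in all 7 accessions. The number of called probe sets was sensitive to the pseudocount, and with 64 added to the signals 49, 55 and 74 were called.

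**Figure D1:**
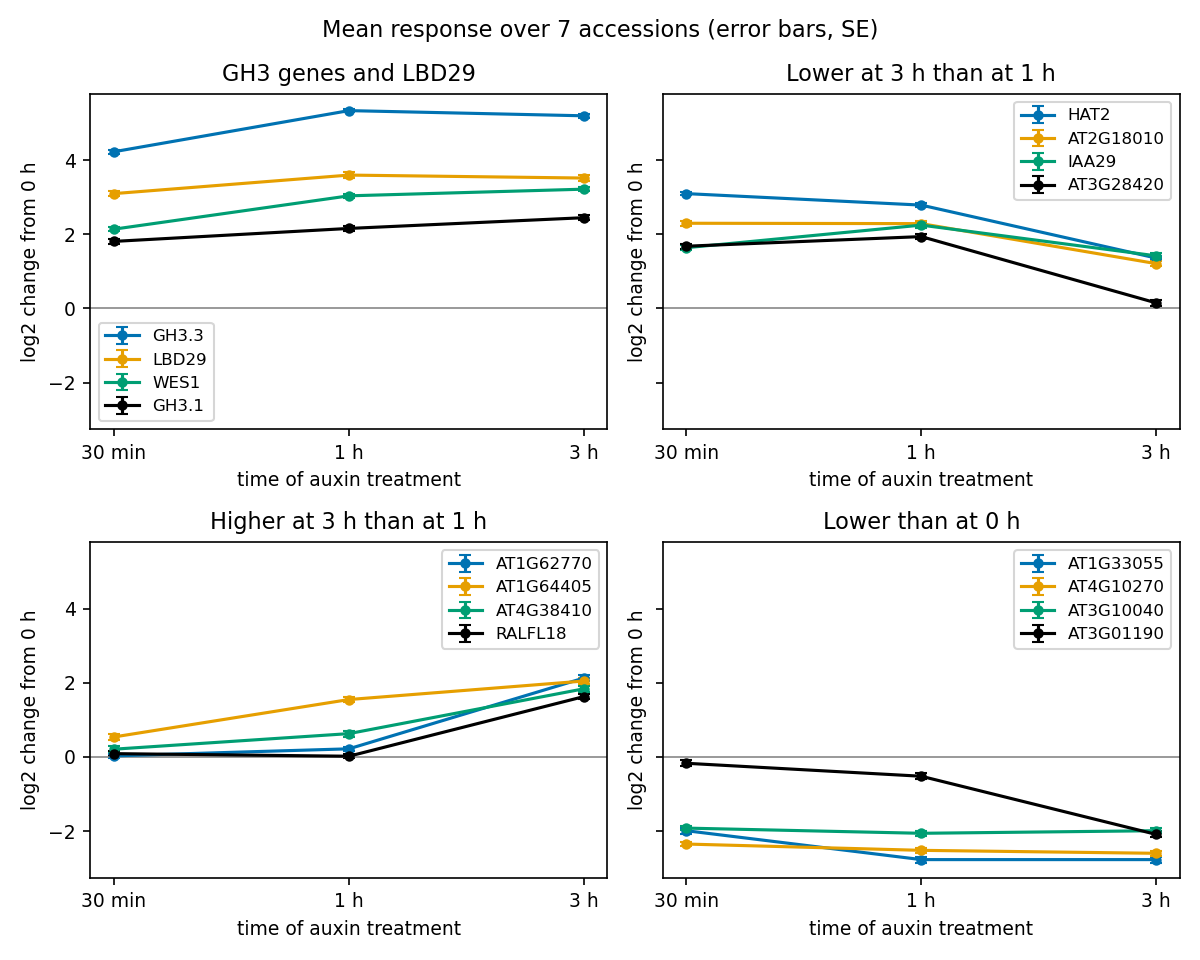
Mean log2 change from 0 h over the 7 accessions (vertical axis) at 30 min, 1 h and 3 h of auxin treatment (horizontal axis) for 16 named genes, with points for the mean and bars for the SE of the model. GH3.3 reached 5.34 at 1 h, HAT2 fell from 3.1 at 30 min to 1.36 at 3 h, AT1G62770 was at 0.22 at 1 h and 2.13 at 3 h, and AT4G10270 lay at -2.35 or lower at each time.

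GH3 auxin-conjugating enzymes rose as a group. Of 4 measured genes, GH3.3, WES1 and GH3.1 rose at each time, the same 3 when adjusted over the list alone. WES1 rose by 2.14 ± 0.05, 3.04 ± 0.05 and 3.22 ± 0.05, and GH3.1 by 1.81 ± 0.07, 2.16 ± 0.07 and 2.45 ± 0.07, while GH3.17 showed -0.24 ± 0.06, -0.36 ± 0.06 and 0.14 ± 0.06 (SE). GH3.1 lay between 2.59 and 14.5 at 0 h, under the pseudocount, so its sizes depended on that choice. They were 0.87 at 30 min (not called), 1.1 at 1 h and 1.31 at 3 h when 64 was added. The list test gave adjusted p = 3.39e-13 at 30 min, 8.95e-11 at 1 h and 1.09e-10 at 3 h, and the calls held with an estimated correlation.

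Aux/IAA repressors, the proteins degraded in auxin signalling, rose in the list test at each time (adjusted p = 7.48e-06, 7.48e-06 and 0.00115), which held with an estimated correlation. Of its 29 named members, 22 matched no probe set listed with 1 gene, and of the 7 matched 3 passed the filter. The result covers those 3 genes alone, since probe sets with no listed gene may measure others. IAA29 rose by 1.64 ± 0.07, 2.25 ± 0.07 and 1.42 ± 0.07, and with a pseudocount of 64 was at 0.85, 1.27 and 0.71, past 2-fold at 1 h alone. IAA30 rose by 1.13 ± 0.05 and 1.56 ± 0.05, with 0.86 ± 0.05 at 3 h, under 2-fold. Its signals at 0 h, 5.21 to 15.1, were under the pseudocount too. With 64 added it was at 0.51 and 0.76 at 30 min and 1 h, not called. IAA18 showed -0.07 ± 0.05, -0.04 ± 0.05 and 0.10 ± 0.05. Adjusted over the list alone, 2, 2 and 1 members were called, as over all probe sets.

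Genes of lateral root initiation rose in the list test (adjusted p = 3.99e-07, 3.42e-08 and 1.55e-05), which held with an estimated correlation. Of 4 measured, LBD29 and LBD16 passed 2-fold at 30 min and 1 h and LBD29 at 3 h, and the counts were the same when adjusted over the list alone. LBD16 rose by 1.81 ± 0.07 and 1.75 ± 0.07, with 0.90 ± 0.07 at 3 h. PUCHI, a factor that acts in the same process, showed 0.17 ± 0.06, 0.69 ± 0.06 and 0.98 ± 0.06, and CR4 -0.06, 0.03 and 0.04. Other lists on auxin held at most 2 measured genes and had no list test. Of the SAUR genes, AT2G18010 rose by 2.30 ± 0.07, 2.29 ± 0.07 and 1.21 ± 0.07 (0.56 at 3 h with a pseudocount of 64, under 2-fold), and AT1G43040 showed 0.05, 0.05 and 0.04. WAG2, a kinase of auxin transport, showed 0.65 ± 0.05, 0.66 ± 0.05 and 0.35 ± 0.06, and the biosynthesis gene YUC2 -0.20 ± 0.05, -0.24 ± 0.05 and -0.31 ± 0.05.

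Among wall proteins, the expansins rose in the list test at 30 min (adjusted p = 0.00403) and 1 h (adjusted p = 0.000661), which held with an estimated correlation, and not at 3 h (adjusted p = 0.305). Of 15 measured, 7 passed the adjusted p upwards and 2 downwards at 30 min, and 8 and 3 at 1 h. EXLA2 was at 1.03 ± 0.06 at 1 h and was the only member past 2-fold at 1 h, also when adjusted over the list alone, and was at 0.99 when a replicate number was left out and 0.67 with a pseudocount of 64. EXLA3 and EXLA1 showed 0.80 ± 0.06 and 0.94 ± 0.07, and EXPB1 -0.53 ± 0.06. Xyloglucan hydrolases rose at 30 min (8 measured, adjusted p = 0.0126, and adjusted p = 0.0702 with an estimated correlation) but not at 1 h (adjusted p = 0.138) or 3 h (adjusted p = 0.835, median -0.17, mean 0.03). XTH18 showed 0.87 ± 0.07, 1.03 ± 0.07 and 1.2 ± 0.07, and XTH19 0.79 ± 0.07, 0.94 ± 0.07 and 1.09 ± 0.07. Past 2-fold were 0, 1 and 2 members at 30 min, 1 h and 3 h, the same when adjusted over the list alone. Either of 2 arrays ended the call of XTH18 at 1 h, with the lower value, 0.99, without C24 1 h replicate 3. A pseudocount of 64 ended it too (0.94), as it did for XTH19 at 3 h. The U-box ubiquitin ligases, a family added after the files were given, rose at 30 min and 1 h (7 measured, adjusted p = 1.02e-05 and 0.000126), which held with an estimated correlation, but not at 3 h (adjusted p = 0.073). PUB23 rose by 1.13 ± 0.05 at 30 min (0.85 with a pseudocount of 64, not called), and PUB26 was at 0.70 ± 0.05 at 1 h.

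Photosynthesis genes of the shoot fell at 3 h (5 measured, all 5 past the adjusted p downwards, adjusted p = 0.0113, and adjusted p = 0.236 with an estimated correlation), by 0.61 ± 0.06 for LHCB4.2 and 0.29 ± 0.05 for RCA on the log2 scale. Their medians were -0.01 at 30 min (adjusted p = 0.942) and -0.08 at 1 h (adjusted p = 0.371). Touch and rapid stress genes had no common direction (4 measured, adjusted p = 0.624, 0.237 and 0.746): CML38 showed -0.87 ± 0.07 and WRKY53 0.99 ± 0.06 at 1 h. In limma 0 members of either list were called, also when adjusted over the list alone and at an unadjusted p under 0.05, since their mean changes were under 2-fold. By the adjusted p and at any size, 1 touch gene was up and 3 were down at 30 min, 2 and 1 at 1 h, and 2 and 2 at 3 h. Among pairs of genes with no list test, the root markers EXPA7 and EXPA18 showed 0.99 ± 0.08 and 0.47 ± 0.07 at 3 h, the response regulators ARR15 and RR16 -0.54 ± 0.08 and -0.52 ± 0.04, LTI30 and COR47 of the abscisic acid and cold list 0.90 ± 0.07 and 0.29 ± 0.04, and the glucosinolate genes BCAT4 and AOP3 -0.86 ± 0.05 and -0.12 ± 0.08. The clock gene GI showed 0.55 ± 0.05 at 3 h and the defence gene SAG101 0.15 ± 0.09.

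A different set of genes was lower. AT4G10270, a member of the wound-responsive family, fell by 2.35 ± 0.06, 2.52 ± 0.06 and 2.60 ± 0.06 on the log2 scale at 30 min, 1 h and 3 h from signals at 0 h between 319 ± 62.4 in Fei-0 and 946 ± 22.3 in Sha (SD, n = 3). AT1G33055 fell by 1.99 ± 0.08, 2.77 ± 0.08 and 2.77 ± 0.08, and AT3G10040, a transcription factor gene induced by low oxygen, by 1.92 ± 0.06, 2.06 ± 0.06 and 1.99 ± 0.06 (SE; adjusted p = 1.04e-40 at 1 h). All 3 were lower in each of the 7 accessions. AT4G25250, of the pectin methylesterase inhibitor family, fell by 1.37 ± 0.09 at 1 h and 1.78 ± 0.09 at 3 h. With a pseudocount of 64 it was at -0.69 and -0.85, not called. The peroxidase gene AT3G01190 showed -0.17 ± 0.08 and -0.52 ± 0.08 at the early times and fell by 2.09 ± 0.08 at 3 h. No mock-treated arrays are labelled, so a change from 0 h holds the effect of handling and of time as well as of auxin. The titles number the times in turn, so such a change may also hold an order or batch of processing.

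The direct tests between times asked how the response moved. From 1 h to 3 h AT1G62770, of the pectin methylesterase inhibitor family, rose by 1.91 ± 0.07, and the pectate lyase gene AT1G67750 by 1.60 ± 0.04 on the log2 scale (SE; adjusted p = 5.9e-37 and 3.22e-43). RALFL18, a peptide signal of the rapid alkalinization family, rose by 1.61 ± 0.06, and AT1G30760, a berberine bridge enzyme-like gene, by 1.78 ± 0.08. HAT2 fell by 1.44 ± 0.05 (adjusted p = 8.61e-36), AT3G28420 by 1.79 ± 0.07 and AT5G52670 by 1.79 ± 0.09 over the same step, and the peroxidase genes AT3G01190 and AT1G14550 by 1.57 ± 0.08 and 1.45 ± 0.07. Signals of RALFL18 at 0 h ran from 0.697 in Col-0 to 19.6 in Bl-1. With a pseudocount of 64 the steps of RALFL18 (0.74), AT3G28420 (-0.90), AT5G52670 (-0.95) and AT1G14550 (-0.62) were not called. From 30 min to 1 h the largest named rises were those of WRKY53, 1.25 ± 0.06, GH3.3, 1.11 ± 0.05, AT2G39980, 1.07 ± 0.05, AT4G37295, 1.06 ± 0.07 (0.98 when a replicate number was left out), and ARL, a growth regulator, 1.04 ± 0.05. With a pseudocount of 64 WRKY53 (0.92), AT2G39980 (0.75), AT4G37295 (0.70) and ARL (0.95) were not called and GH3.3 was. In limma 11 probe sets were higher and 0 lower at 1 h than at 30 min, with 0 lower by 2-fold and 2463 lower by any amount at an unadjusted p under 0.05. From 1 h to 3 h 29 were higher and 60 lower.

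Each accession was then compared with its own 0 h arrays. GH3.3 had the largest rise of a named gene at 1 h in each accession, with 6.23 in Bur-0, 5.88 in Sha, 5.29 in Bay-0, 5.24 in Bl-1, 5.22 in C24, 4.89 in Fei-0 and 4.62 in Col-0 (log2 change, SE 0.14, n = 3 and 3). AT1G33055 fell in all of them at 1 h, from 2.1 on the log2 scale in Fei-0 to 3.42 in Bl-1 (SE 0.21). In C24 the largest rise beside GH3.3 was that of AT1G26250, of the extensin family, 3.34 ± 0.29 at 1 h.

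At 1 h 183 probe sets were higher and 39 lower in Bay-0, 144 and 77 in Bl-1, 303 and 163 in Bur-0, 176 and 75 in C24, 243 and 41 in Col-0, 111 and 37 in Fei-0, and 200 and 69 in Sha. Both directions together gave 218, 222 and 482 probe sets in Bay-0 at 30 min, 1 h and 3 h, 267, 221 and 310 in Bl-1, 316, 466 and 626 in Bur-0, 201, 251 and 423 in C24, 241, 284 and 431 in Col-0, 112, 148 and 239 in Fei-0, and 229, 269 and 390 in Sha. The counts themselves were not compared by a test, and Fei-0 had 2 arrays at 3 h.

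**Figure D2:**
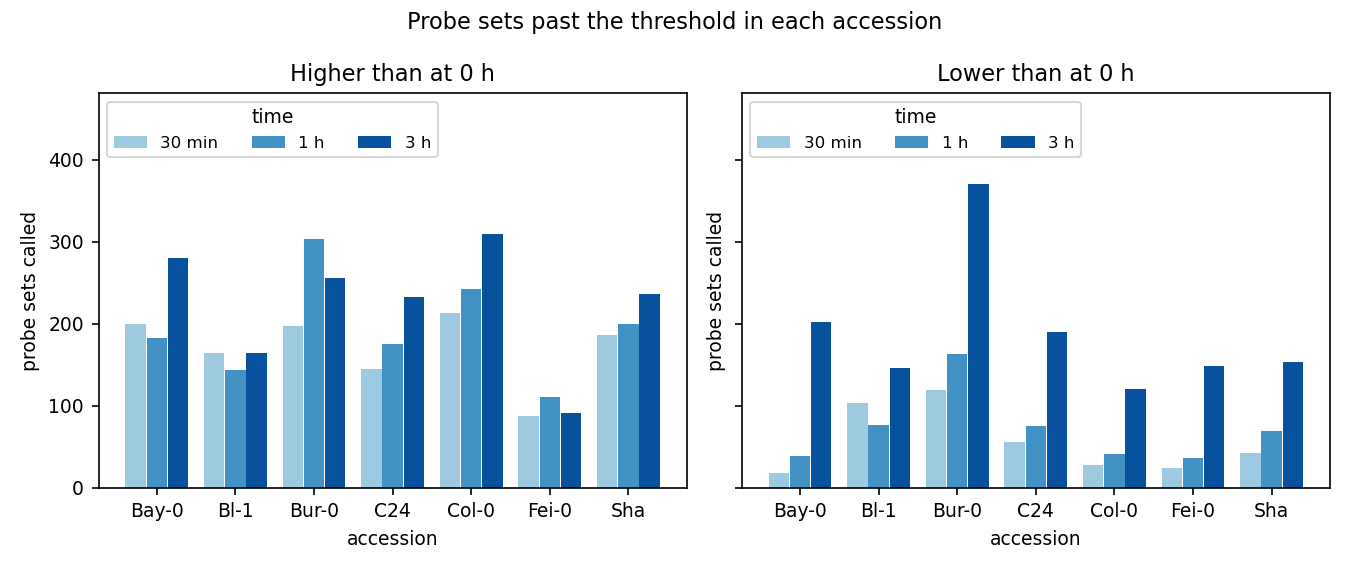
Number of probe sets past the threshold (vertical axis) that were higher (left) or lower (right) than at 0 h in each accession (horizontal axis), with 1 bar per time. Bur-0 had the highest number of lower probe sets at 3 h, 370, and Fei-0 the lowest number of higher ones at 30 min, 88.

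Calls were shared between accessions that have separate 0 h arrays. At 1 h 51 probe sets were higher in all 7 accessions, where 4.65e-10 would be expected from independent draws, and 4 were lower in all 7. The higher ones held GH3.3, LBD29, WES1, HAT2, AT2G18010, IAA29, GH3.1, LBD16 and IAA30, and the lower ones AT1G33055, AT4G10270, AT3G10040 and a probe set with no listed gene. Between pairs at 1 h, 158 were higher in both Bur-0 and Col-0 (4.6 expected), 133 in both Bay-0 and Sha (2.3 expected), and 75 in both Bl-1 and Fei-0 (1 expected). At 3 h 38 were higher and 18 lower in all 7. At 1 h 810 probe sets were called in at least 1 accession, 415 of them in exactly 1, which does not show that the others differed.

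The difference in response between accessions was tested directly. The 8 genes with the smallest p at each time held none of the auxin genes above, and STZ was among them at each time. STZ, a zinc-finger repressor of stress responses, rose in Col-0 from a signal of 470 ± 41.8 at 0 h to 1278 ± 73.5 at 1 h and in Bur-0 from 255 ± 31.9 to 1063 ± 57.3, and fell in Bay-0 from 269 ± 66.4 to 87.3 ± 7.71 and in Sha from 231 ± 103 to 83.3 ± 5.81 (SD, n = 3). Its responses spanned 2.76 at 30 min, 3.44 at 1 h and 3.1 at 3 h (adjusted p = 5.97e-19, 4.19e-23 and 9.76e-23). AT4G29780 had responses at 3 h from -1.14 ± 0.16 in Sha to 2.48 ± 0.16 in Bur-0. AT5G03350, a lectin-like defence gene, fell in Bl-1 by 2.76 ± 0.20 at 30 min and showed 0.82 ± 0.20 in Bay-0.

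All 4 measured touch and rapid stress genes, STZ, CML38, WRKY53 and WRKY22, differed in response between accessions at each time. Of the auxin genes, GH3.3 differed at each time, over a range of 1.5, 1.60 and 1.23 (adjusted p = 4.08e-09, 2.17e-09 and 8.95e-08), from a 0 h signal of 31.0 ± 10.3 in Sha to 121 ± 16.9 in Col-0 (SD, n = 3). Among the 4 measured GH3 genes 2 differed at each time, and WAG2 differed at each time too. HAT2 differed at 30 min over 1.21, from 2.58 in Bl-1 to 3.79 in Sha. It also differed at 1 h over 1.02, where leaving out any 1 of 3 arrays ended the call. Of the 4 measured lateral root genes, 0, 0 and 1 differed at 30 min, 1 h and 3 h. The 3 measured Aux/IAA genes and YUC2 were not called at any time. LBD29 did not pass the test (adjusted p = 0.116, 0.111 and 0.219). Expansins differed in 6, 4 and 7 of 15 members, among them EXPA8, which at 3 h fell in Bur-0 by 1.78 ± 0.20 and rose in Bay-0 by 2.08 ± 0.20.

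In all, 1456, 1167 and 1785 probe sets differed at 30 min, 1 h and 3 h, or 9.1%, 7.3% and 11.2% of those tested, with a median range of 1.25 to 1.27. Only 40, 21 and 46 of them were called higher in 1 accession and lower in another. The differing probe sets included 63 of the 116, 79 of the 153 and 124 of the 203 called in the mean. Fewer probe sets, 712, 810 and 1346, had a called response in at least 1 accession. A range of 1 over the accessions can thus be reached with no called 2-fold response in any of them. The lowest of the 7 responses was most often that of Bur-0 (483 probe sets at 30 min, 316 at 1 h, and the most at 3 h too), and the highest that of Sha at 30 min (413) and of Bay-0 at 1 h and 3 h (286 and 539). Each accession's arrays may share a batch, which the labels do not give, and the batch and the accession cannot be told apart.

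**Figure D3:**
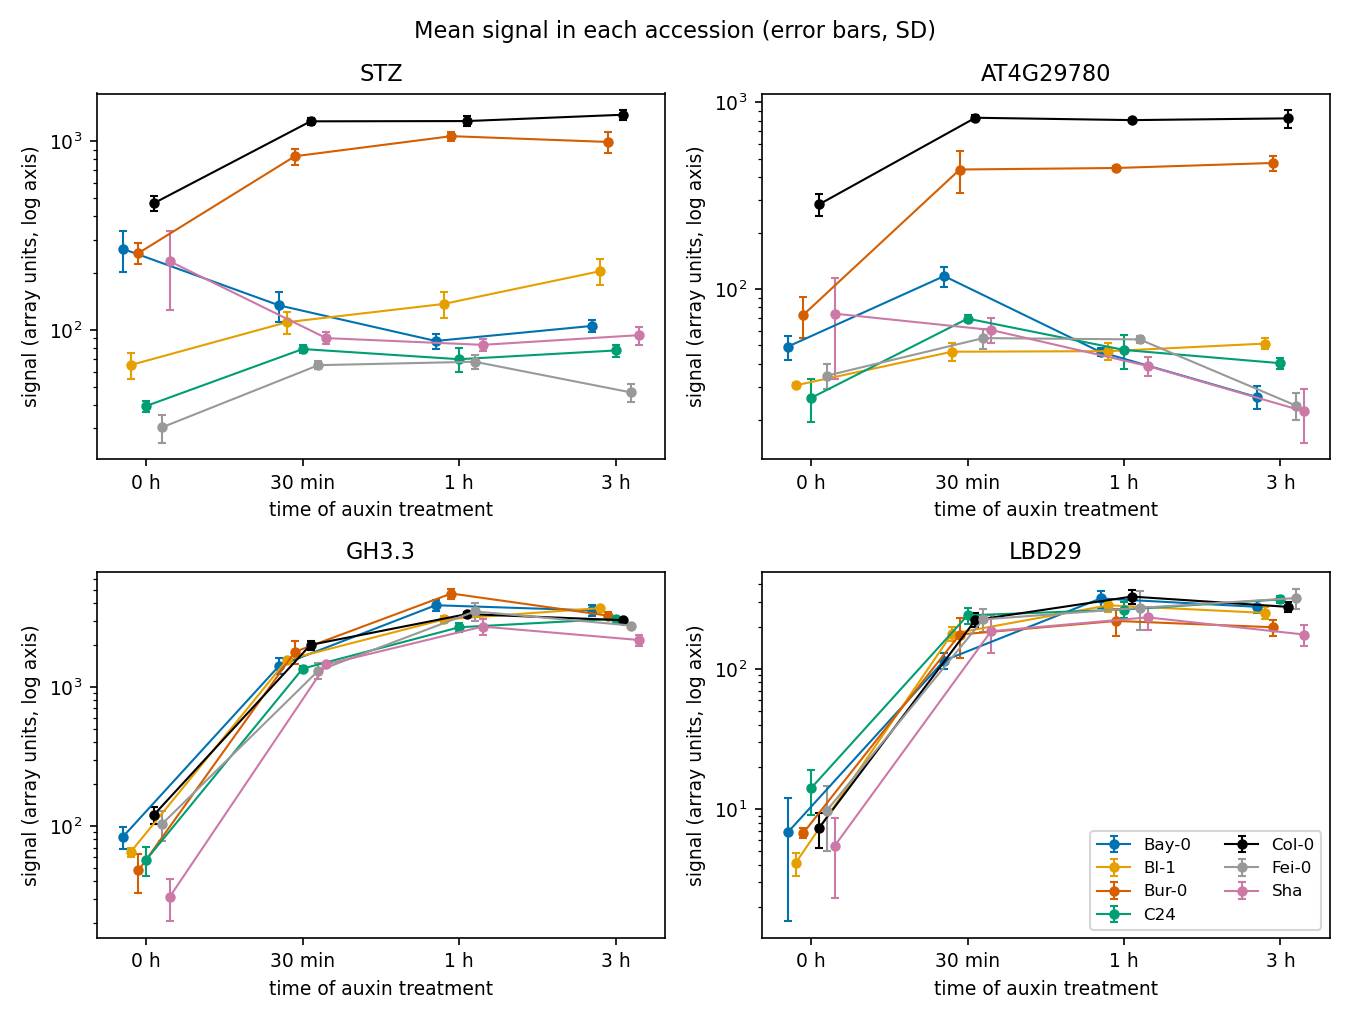
Mean signal (vertical log axis, array units) of STZ, AT4G29780, GH3.3 and LBD29 at 0 h, 30 min, 1 h and 3 h (horizontal axis) in the 7 accessions, with bars for the SD of 3 arrays (2 for Fei-0 at 3 h). STZ in Col-0 went from 470 to 1278 at 1 h and in Bay-0 from 269 to 87.3, while GH3.3 in Bur-0 went from 47.9 to 4691.

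As list scores, the response of the GH3 genes differed between accessions at 30 min, from 1.64 ± 0.07 in Fei-0 to 2.34 ± 0.11 in Sha (SE; permutation test, adjusted p = 0.0013), and at 1 h, from 2.21 ± 0.12 in C24 to 2.81 ± 0.09 in Sha (permutation test, adjusted p = 0.0013). At 3 h it ran from 2.50 in Fei-0 to 2.90 in C24 (permutation test, adjusted p = 0.084). The SAUR score, over 2 genes, differed at 30 min, from 0.77 ± 0.12 in Bur-0 to 1.52 ± 0.07 in C24 (permutation test, adjusted p = 0.00036), and at 1 h, from 0.91 ± 0.05 in Sha to 1.51 ± 0.14 in C24 (permutation test, adjusted p = 0.0029), but not at 3 h, from 0.42 in Col-0 to 0.81 in C24 (permutation test, adjusted p = 0.21). The Aux/IAA score differed at 3 h, from 0.47 ± 0.12 in Bl-1 to 1.06 ± 0.08 in C24 (permutation test, adjusted p = 0.0029), but not at 30 min (0.76 to 1.10, permutation test, adjusted p = 0.28) or 1 h (1.15 to 1.45, permutation test, adjusted p = 0.18). By single genes at 30 min, AT2G18010 had a range of 0.97 (adjusted p = 0.0275) and AT1G43040 of 0.79 (adjusted p = 0.00255), and at 1 h 0.99 (adjusted p = 0.00336) and 0.61 (adjusted p = 0.0908), so neither SAUR gene passed the range threshold at these times, and AT2G18010 did at 3 h (1.27). None of the Aux/IAA genes passed it at 3 h, where IAA29 had a range of 0.9 (adjusted p = 0.0232) and IAA30 of 0.76 (adjusted p = 0.00278). At 0 h AT2G18010 lay between 0.994 in Bay-0 and 22.8 in Bur-0, near or under the pseudocount. The response was above 0 in each accession for all 3 scores. Which accession stood at either end changed with the pseudocount: with 1 added, the SAUR score at 1 h ran from 1.16 in Bur-0 to 2.77 in Bay-0, the Aux/IAA score at 3 h from 0.8 in Bl-1 to 2.26 in Bay-0, and the highest GH3 score was that of Bur-0 at 30 min (2.77) and 1 h (3.33).

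Levels before treatment differed widely between accessions. The alpha-tubulin gene TUA6 lay at 2380 ± 191 in Bur-0 and 1828 ± 62.7 in Col-0 but at 104 ± 31.8 in Sha and 118 ± 7.21 in Fei-0 (signal, SD, n = 3; adjusted p = 8.76e-51). QQS, which acts in starch metabolism, lay at 856 ± 125 in Fei-0 and at 8.16 or less in the other accessions. The glucosinolate genes differed: AOP3 lay at 725 ± 81.4 in Bay-0 and 445 ± 36.7 in Bl-1 and at 5.13 or less elsewhere, and AT2G25450, whose enzyme modifies glucosinolate side chains, from 15.2 ± 1.83 in C24 to 1893 ± 255 in Fei-0. CSA1, of the resistance gene family, lay at 256 in Fei-0 and 1.53 in Bl-1.

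At 0 h 3671 probe sets differed, 23.1% of those tested, with a median range of 1.36. Wide ranges of named genes were those of AT2G25510, from a signal of 13.5 in Sha to 5080 in Bay-0, AT5G23830, from 5.69 in Fei-0 to 1630 in Bay-0, and ECS1, from 8.60 in C24 to 1550 in Col-0. Their low ends lay under the pseudocount, so the log2 range depended on it, and that of AT2G25510 was 7.54, 9.04 with 1 added and 6.07 with 64 added. Of the lists, 3 of the 4 touch and rapid stress genes differed, with STZ at 470 in Col-0 and 30.4 in Fei-0, as did 6 of 15 expansins, with EXPA8 at 348 in Fei-0 and 10.5 in Bay-0, and 3 of 5 shoot photosynthesis genes, with LHCB4.2 at 3740 in Bur-0 and 555 in Sha. Among auxin genes GH3.3 and GH3.17 of the 4 GH3 genes differed (GH3.17 by 1.03, and by 0.95 without Bl-1 0 h replicate 2, 1 of 2 arrays that ended its call), and IAA29 did, from 2.73 in Bay-0 to 28.5 in Bur-0 (a range of 1.26, and 0.47 with a pseudocount of 64, not called). The 2 measured SAUR genes differed as well, AT1G43040 by 1.35 and AT2G18010 by 1.18 (0.42 with a pseudocount of 64, not called). Against Col-0, 1086 probe sets differed in Bay-0, 833 in Sha, 609 in Bur-0, 570 in Fei-0, 549 in C24 and 497 in Bl-1. The probes of the array are of the Col-0 sequence, so a lower signal in another accession can also reflect a mismatch.

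**Figure D4:**
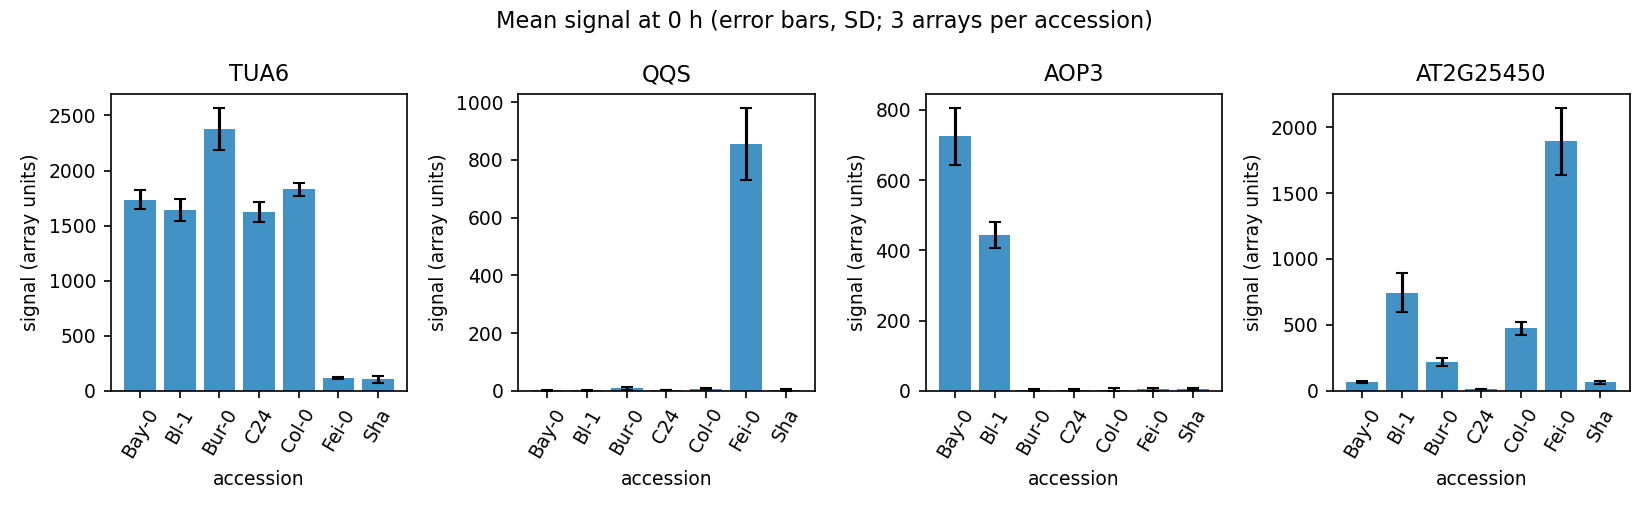
Mean signal at 0 h (vertical axis, array units) of TUA6, QQS, AOP3 and AT2G25450 in the 7 accessions (horizontal axis), with bars for the mean of 3 arrays and error bars for the SD. TUA6 was low in Sha (104) and Fei-0 (118), QQS was high in Fei-0 (856), AOP3 was high in Bay-0 (725) and Bl-1 (445), and AT2G25450 was highest in Fei-0 (1893).

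Of the gene families added after the files were given, the SWEET sugar transporters fell at 3 h (7 measured, 5 past the adjusted p downwards, adjusted p = 0.0297, which held with an estimated correlation), with SWEET17 at -0.81 ± 0.07 and SWEET2 at -0.74 ± 0.06. The UDP-glycosyltransferases fell at 3 h (34 measured, 16 down and 8 up by the adjusted p, adjusted p = 0.0297, and adjusted p = 0.122 with an estimated correlation). The glutathione S-transferases fell at 3 h (12 measured, 6 down and 2 up, adjusted p = 0.0309, and adjusted p = 0.0655 with an estimated correlation), with GSTU26 at -1.24 ± 0.08 (-0.92 with a pseudocount of 64, not called). The bZIP factors rose at 1 h (14 measured, 8 up and 1 down, adjusted p = 0.00761, which held with an estimated correlation) and at 30 min (adjusted p = 0.0368, and adjusted p = 0.0869 with an estimated correlation), with BZIP61 at 0.62 ± 0.06 at 1 h. Genes of the plastid ribosome and RNA polymerase fell at 30 min (18 measured, 5 down, adjusted p = 0.0297, and adjusted p = 0.579 with an estimated correlation), and after quantile normalization the adjusted p was 0.0578.

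The other 16 families had no list call with camera at any time. With fry, which does not compare a list with other genes, 23 of their 48 tests passed, among them tetraspanins (adjusted p = 1.83e-08) and calmodulin-like genes (adjusted p = 1.31e-07) at 30 min, tubulins at 1 h (adjusted p = 7.25e-07), and trichome birefringence-like genes (adjusted p = 1e-12) and RALF-like peptides (adjusted p = 5.25e-07) at 3 h. The adjusted p of camera at 30 min, 1 h and 3 h was 0.746, 0.942 and 0.587 for beta-glucosidases, 0.716, 0.829 and 0.638 for CYP71B cytochromes, 0.0872, 0.835 and 0.671 for tetraspanins, 0.942, 0.624 and 0.0601 for trichome birefringence-like genes, and 0.166, 0.118 and 0.78 for GH9 endoglucanases. For calmodulin-like genes it was 0.0953, 0.948 (median 0.09, mean -0.04) and 0.661 (median 0.02, mean -0.07), for RALF-like peptides 0.203, 0.404 and 0.78, for tubulins 0.378, 0.125 and 0.404, for IQ-domain proteins 0.532, 0.942 and 0.784, for glutamate receptor-like genes 0.78, 0.873 and 0.587, and for defensins 0.623, 0.829 and 0.829. For plastid-encoded photosystem genes it was 0.371, 0.942 and 0.371, for plastid-encoded NDH genes 0.639, 0.911 and 0.497, for mitochondrion-encoded genes 0.632, 0.497 and 0.872, for mitosis genes 0.109, 0.638 and 0.78, and for nuclear RNA polymerases 0.45, 0.639 and 0.109. Members could still change alone, as RALFL18 did at 3 h, by 1.63 ± 0.06 (0.75 with a pseudocount of 64, not called).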

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

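The tests on RNA quality, 0 h arrays, probe sequence and hypoxia genes were chosen only after the results they bear on were seen, and what each would show was written down before its value was known. The counts of other splits, quantile normalization, the contrasts, thresholds and the 28 fixed gene lists were chosen before the data were examined.

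Responses that differed between accessions in a direct test stood out, with 1456 probe sets at 30 min, 1167 at 1 h and 1785 at 3 h. Residuals of a model of accession plus time were shuffled within each time. Among 100 sets, the real one included, the highest other count was 91, 40 and 250 and only 1 was as large. A chance ordering of these arrays can be excluded at each time, though the shuffled residuals still held the real differences as spread. Chance differences between cultures cannot be excluded, since the arrays of a group may share a culture. At 30 min the responses spanned 2.76 on the log2 scale for STZ, 3.22 for AT3G18250, 2.34 for AT1G23390, 3.58 for AT5G03350, 3.31 for CCL, 3.98 for AT5G24210, 2.06 for AT2G38870 and 3.03 for AT5G52760. At 1 h they spanned 3.44 for STZ, 2.73 for AT3G18250, 3.01 for AT4G29780, 5.95 for AT1G26250, 2.41 for AT4G27652, 2.17 for AT1G76600, 3.65 for AT1G76640 and 2.50 for AT1G19210. At 3 h they spanned 3.87 for AT3G18250, 3.1 for STZ, 3.62 for AT4G29780, 3.02 for AT1G23390, 3.02 for AT4G27652, 3.14 for AT5G48490, 3.86 for EXPA8 and 2.09 for AT4G24380. The response of a list differed for Aux/IAA repressors at 3 h (permutation test, adjusted p = 0.0029, from 0.47 in Bl-1 to 1.06 in C24) and for GH3 genes at 30 min (permutation test, adjusted p = 0.0013, from 1.64 in Fei-0 to 2.34 in Sha) and 1 h (permutation test, adjusted p = 0.0013, from 2.21 in C24 to 2.81 in Sha). It also differed for SAUR genes at 30 min (permutation test, adjusted p = 0.00036, from 0.77 in Bur-0 to 1.52 in C24) and 1 h (permutation test, adjusted p = 0.0029, from 0.91 in Sha to 1.51 in C24). Neither measured SAUR gene passed the range threshold alone at these times, and no Aux/IAA gene did at 3 h.

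The number of probe sets that differed in response was weighed first. The scaling between arrays is argued against as its whole cause, since 1183 probe sets differed at 1 h after quantile normalization. That step was applied to the deposited, already scaled signals, so earlier steps of the authors' processing were not tested. With the GAPDH ratio in the model, 1040 differed at 1 h, which argues against an effect that follows that ratio as the whole cause. The slope of the ratio rests on arrays within groups, and the actin ratio, which ranged more widely, was not in the model. RNA quality in general therefore stays open. Unusual 0 h arrays of some accessions cannot account for the step from 1 h to 3 h, which uses none of them and differed in 632 probe sets. Of these, 339 were among the 1167 that differed in response at 1 h. That step is another contrast, so how much of the 1167 came from the 0 h arrays stays open. A batch of an accession's arrays, or its handling, cannot be told apart from the accession, and a biological difference between accessions stays open and untested.

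Levels at 0 h were weighed next, with 3671 probe sets called and 1640 in the highest of the other splits (1 of 100 splits as large). A chance ordering of these arrays can be excluded, but chance differences between cultures cannot, as the arrays of a group may share a culture. The scaling between arrays is argued against, with 3665 called after quantile normalization, while earlier steps of the authors' processing were not tested. A mismatch to the probes of the Col-0 sequence would lower the other accessions, and Col-0 alone was lower in 6 probe sets and alone higher in 32. Over the 6 other accessions 170 were alone lower and 104 alone higher, and lower ones outnumbered higher ones in Bl-1 (19 and 12), Bur-0 (27 and 7), C24 (23 and 5), Fei-0 (27 and 8) and Sha (38 and 14) but not in Bay-0 (36 and 58), so probe sequence and transcript level cannot be told apart from these values. Only 312 of the called probe sets had 1 accession standing alone, and a difference between the accessions stays open and untested.

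The fall of AT4G10270, AT1G33055 and AT3G10040 after 0 h was the last pattern, weighed on other genes known from hypoxia. Of 17 such genes not seen before, 8 were lower and 4 higher at 30 min (camera, p = 0.00637, and p = 0.0817 with an estimated correlation), so a shared hypoxia programme stays open. AT5G26200 was at -0.87 ± 0.05 and AT4G24110 at -0.85 ± 0.08, while PDC2 was at 0.15 ± 0.05 (SE, 7 accessions; chosen after their values were seen). The prediction was written for 30 min alone. Later times were looked at only after the results were seen. Of the same 17 genes, 11 were lower and 2 higher at 1 h, and 10 were lower and 4 higher at 3 h. The scaling between arrays is argued against, since all 13 listed genes lower at 30 min stayed lower under quantile normalization and median centring. Earlier steps of the authors' processing were not tested. Handling at the start of treatment was not tested, as no mock-treated arrays are labelled.

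For the mean response, 1 of 100 splits was as large and the highest other count was 0. A chance ordering of these arrays can be excluded for the 97, 129 and 109 higher and the 19, 24 and 94 lower probe sets. Chance differences between cultures cannot, since the arrays of a group may share a culture. The same held for the steps, with 11 and 89 probe sets and 0 in the highest other split. For single accessions 10 splits are too few to give a share under 0.05. The real counts at 30 min, 1 h and 3 h, with the highest other count, were 218, 222 and 482 in Bay-0 (1, 1 and 4), 267, 221 and 310 in Bl-1 (0, 0 and 0), 316, 466 and 626 in Bur-0 (26, 6 and 11), 201, 251 and 423 in C24 (1, 15 and 0), 241, 284 and 431 in Col-0 (1, 1 and 2), and 229, 269 and 390 in Sha (5, 2 and 6). For Fei-0 they were 112 and 148 at 30 min and 1 h (0 and 3).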

How the results depend on the processing

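The GAPDH covariate, the steps without each accession and the responses without Bur-0 were tests chosen only after the results were seen. Mean responses, steps and single-accession responses of named genes kept their direction in every alternative run on them. Ranges over accessions carry no sign, so a reversal could not show in them. Named genes were not rerun with an accession left out or with a separate model per accession. Not every call held. Of 535 called values of named genes, 164 were no longer called with a pseudocount of 64, and 83 in at least 1 run with an array or replicate number left out. It was 22 with the GAPDH covariate, 13 after median centring, 10 after quantile normalization, 6 with no filter and 2 with the replicate block. With a pseudocount of 1 it was 15 of 502. With the lowest 50% left out, 413 of the values remained and all stayed called. Counts moved by over 1.5 times only with the pseudocount. Quantile normalization, median centring, no filter, a filter at the lowest 50%, a separate model per accession, the GAPDH covariate and leaving out arrays or accessions moved no count that far. Replicate numbers did not pair the samples as a whole (mean correlation 0.01 for the same number and -0.01 for others, 18 of 123 pairs over 0.1), though in Fei-0 it was 0.09 and -0.04, with 7 of 15 pairs over 0.1, and the block gave 261 calls in Fei-0 at 3 h where 239 stood. With the number as a block the mean counts were 97 and 19, 129 and 24, and 108 and 93 higher and lower. Leaving out 1 array or 1 replicate number gave 94 to 103 higher at 30 min. The pseudocount acts on low signals, and signal over background limits what is called among them.

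With a pseudocount of 1, higher and lower mean responses were 182 and 31 at 30 min, 215 and 69 at 1 h, and 208 and 210 at 3 h. Steps were 32 and 207, differences at 30 min 2260 and levels at 0 h 5760. Responses at 30 min, 1 h and 3 h were 473, 419 and 876 in Bay-0, 504, 439 and 606 in Bl-1, 618, 962 and 1219 in Bur-0, 323, 489 and 806 in C24, 386, 483 and 747 in Col-0, 192, 338 and 527 in Fei-0, and 562, 483 and 662 in Sha.

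With a pseudocount of 64, higher and lower mean responses were 44 and 5, 51 and 4, and 47 and 27. Steps were 1 and 29, differences 525, 415 and 711, and levels at 0 h 1567. Responses were 65, 89 and 194 in Bay-0, 109, 82 and 116 in Bl-1, 114, 184 and 260 in Bur-0, 75, 89 and 160 in C24, 93, 112 and 147 in Col-0, 48, 57 and 79 in Fei-0, and 84, 100 and 144 in Sha. These calls need larger absolute changes by construction.

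With an estimated correlation the adjusted p was 0.0702 for xyloglucan hydrolases at 30 min and 0.236 for photosynthesis genes at 3 h. With fry it was 1.14e-09 for xyloglucan hydrolases at 1 h, 5.52e-06 and 0.0477 for touch and rapid stress genes at 1 h and 3 h, 0.0219 for photosynthesis genes at 1 h and 3.53e-07 for expansins at 3 h, where camera called none. The permutation test for lists gave adjusted p = 0.012 for Aux/IAA genes at 1 h with a pseudocount of 1, and 0.022 for GH3 and 0.023 for SAUR genes at 3 h with a pseudocount of 64. The cause of these changes was not tested.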

Other observations

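The sets of genes described here, and the tests of hypoxia genes at 1 h and 3 h, were chosen only after the results were seen. Signals of plastid-encoded genes differed at 0 h, and most were lowest in Bay-0 and highest in Bur-0. Over all 3671 probe sets called at 0 h, Bay-0 was lowest in 1008 and highest in 776, and Bur-0 was lowest in 482 and highest in 619. psaA, of photosystem I, lay at a signal of 1090 in Bur-0 and 130 in Bay-0, ndhG, of the NDH complex, at 303 and 35.4, and the ribosomal gene rps4 at 6110 and 1560, while rps2 lay at 1380 in C24 and 179 in Bay-0 (mean of 3 arrays; adjusted p = 3.94e-09, 1.27e-12, 5.19e-20 and 7.27e-19). Of 26 photosystem genes 20 were called, with Bay-0 lowest in 17 and Bur-0 highest in 13 of all 26. Of 9 NDH genes 8 were called, with Bay-0 lowest in 8 and Bur-0 highest in 8 of all 9. Of 18 plastid ribosome and RNA polymerase genes 10 were called, with Bay-0 lowest in 13 and Bur-0 highest in 11 of all 18. Sha was low as well, lowest in 8 of the 26 photosystem genes, with mean deviations of -0.38 in the photosystem and NDH genes, where Bay-0 had -0.65 and -0.83. Of 5 nuclear shoot photosynthesis genes 3 were called, and mean deviations were -0.68 in Bay-0, -0.66 in Sha and 0.55 in Bur-0. Of 11 mitochondrion-encoded genes 3 were called, with Fei-0 lowest in 4 and Bay-0 highest in 4 of all 11.

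STZ, ORA47, PUB22 and AT1G76640 were among 30 probe sets that differed at 30 min and were higher by 2-fold in Bur-0 and Col-0 alone. The next pair, Bl-1 and Col-0, had 18 and Bay-0 and Sha had 9.

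For hypoxia genes at 1 h, 11 of 17 were lower and 2 higher (camera, p = 4.37e-09, and p = 0.000345 with an estimated correlation), and at 3 h 10 and 4 (p = 0.000155, and p = 0.0171 with an estimated correlation).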
